A study of Mus musculus with 21 samples.

How the data were processed

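RNA was measured in 21 libraries of cells sorted from mouse bone marrow, 15 of long-term haematopoietic stem cells (LT-HSC) and 6 of multipotent progenitors (MPP). Per the labels' protocols, lineage-negative cells of pooled animals were sorted by flow cytometry, 5 ng of total RNA per library was amplified to cDNA with the Ovation RNA-seq v2 kit, libraries were made with Nextera XT, and paired-end reads were sequenced on an Illumina NovaSeq. Groups, replicate numbers and batches are those of the labels. Batch 1 holds LT-HSC and MPP of floxed controls and of RXR knockouts, 3 libraries each. Batch 2 holds LT-HSC only, with 3 libraries each of a Vav1-Cre control without floxed alleles, of RXR knockouts, and of RXR knockouts that also carry a floxed Myc-family allele. The labels write that allele as Mycl in the titles and as Myc in the descriptions, so it is called the Myc allele here. No sample was left out or moved between groups.

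The expression values are deposited TPM (transcript abundances on a fixed scale per library) per Ensembl gene, and per the submitters' processing notes kallisto was used with the mouse build mm10. The kallisto version, the transcript set and the way transcripts were summed to genes are not given in the sources used here. Columns of TPM sum to 691094 to 918942 over 28987 gene identifiers, so part of each library's TPM lies outside the deposited table. TPM keep no depth, so the number of reads behind a value is unknown and no interval for counting error is given. Of the identifiers, 27458 (94.73%) had a symbol in the reference table of gene names, and 2 symbols stand for more than 1 identifier. Gene positions are from the RefSeq gene table for GRCm38, the assembly that mm10 names.

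The splicing values are deposited as fractions of 0 to 1 (percent spliced in, PSI) for 46443 events in 7339 genes, each the share of reads on an examined junction against competing junctions. Per the submitters' processing notes STAR 2.6 was used with mm10, and the event caller and its read minimum are not stated. The table was already selected, since the lowest of its values for the spread over all libraries is 0.15. A value was present in all libraries for 27278 events, and 27548 events are of the intron retention type.

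Genes with at least 1 TPM in at least 3 libraries of a fit were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, on log2(TPM + 1). The pseudocount of 1 means that fold changes of genes with low TPM are understated. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene is said to have risen or fallen where its adjusted p was under 0.05. The comparison of all LT-HSC knockouts with all LT-HSC controls had batch as a term. Contrasts within batch 1 came from a fit of its 12 libraries, and those within batch 2 from a fit of its 9 libraries. Differences of the knockout effect between batches and between cell types were tested as interaction terms. The p-values measure the spread between samples of pooled animals. TPM of Rxra, Rxrb and Myc were compared with exact two-sided permutation tests, whose smallest possible p is 0.1 for 3 against 3 libraries. PSI was tested with limma for events that had a value in every library of a fit, with an adjusted p under 0.05 and a difference of at least 0.1 in mean PSI. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

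The deposited TPM set each gene against whatever else fills its library, so every comparison was also fitted after dividing each library by a median-of-ratios size factor over genes above 0 in all libraries of the fit. Values from that fit are called rescaled.

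Before the data were examined, 32 gene lists were written from general knowledge. They are LXR targets, PPAR targets, retinoic acid receptor targets, RXR partner receptors, Myc targets, ribosome biogenesis, ribosomal proteins, translation factors, oxidative phosphorylation, glycolysis, S phase, G2 and M phase, LT-HSC genes, lymphoid priming, myeloid priming, megakaryocyte and erythroid priming, interferon response, inflammatory NF-kB response, immediate early genes, cholesterol synthesis, unfolded protein response, p53 targets, lysosome and autophagy, splicing factors, and markers of B cells, of T and NK cells, of neutrophils, of monocytes, macrophages and dendritic cells, of erythroid cells, of mast cells, basophils and eosinophils, of endothelial and stromal cells, and sex-linked genes. Each was tested with limma's camera with a preset correlation between genes of 0.01, with camera and an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with all other genes, while fry asks whether the list's own genes move, on balance, one way. Members past the gene test were counted over all genes tested and adjusted over the list alone. A list's median is given relative to the median of all genes in the same fit. The genes that passed in LT-HSC of batch 1 were also taken as lists into the batch 2 libraries. Fold changes of comparisons that share the Cre controls were set beside 50 simulations of unchanged groups.

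The genes named were chosen by a rule fixed together with the lists. In each comparison these are the 10 higher and 10 lower genes with the largest fold change among those past the test, with a mean of at least 5 TPM in the higher group and no overlap between the groups within a batch. Where fewer than 5 passed in a direction, the 5 with the smallest p that met the other conditions were taken and are given as not passing. Interactions have no pair of groups, so the overlap condition was not applied there and the mean was taken over all libraries of the fit. Predicted genes named Gm with a number or ending in Rik, identifiers without a symbol, ribosomal protein pseudogenes and antigen receptor segments were counted and not named. From each list past camera up to 4 members were taken, and from splicing the 5 largest events per comparison. Rxra, Rxrb, Myc and Mycn were taken in every comparison. The text gives only part of the genes that the rule picked. A gene named outside this rule is said to have been chosen after its values were seen. Names ending in os are antisense genes, and it is not stated that reads were assigned by strand, so reads of an antisense gene and of its partner may be mixed.

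The labels number the replicates. MPP and LT-HSC libraries of the same number carry the same animal or pool name in the labels, and their deviations from the group means correlated at 0.193 to 0.701 in knockouts, against -0.509 to 0.372 for other numbers. In floxed controls the same-number values were 0.0707 to 0.198 against -0.255 to 0.136. Knockout and control libraries share only a number.

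The gene fits and camera were tested on simulated data in which 200 genes were changed, and the splicing fits with 200 changed events. At a log2 change of 2 the fits recovered 99% of them for all LT-HSC, 92% for LT-HSC of batch 1, 97% for MPP, 67% for LT-HSC of batch 2 and 64% for the Myc allele, and at a log2 change of 1 they recovered 51%, 61%, 56%, 4% and 4%. A PSI change of 0.4 was recovered in 60% of events for all LT-HSC, 19% for MPP and 4% for the Myc allele.

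Alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios and quantile scaling, array weights, a replicate block, a fit without the batch term, a fit of all 21 libraries, fits of only the 6 libraries compared, and each library left out in turn. For lists they were the estimated correlation and fry. For splicing they were events with missing values, a minimum difference of 0.2 or none, and a logit of PSI with values held between 0.01 and 0.99. Other splits of the same samples were counted, all 10 for 3 against 3 libraries and 100 drawn for larger designs. The reads themselves were not analysed here. Mycl and Rxrg had a mean under 1 TPM in every group and carry no comparison.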

Results

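RNA of sorted blood stem and progenitor cells of the mouse was measured in 21 libraries, 15 of long-term haematopoietic stem cells (LT-HSC), the most primitive blood stem cells, and 6 of multipotent progenitors (MPP), their early offspring. Retinoid X receptors (RXR) are nuclear receptors that pair with the receptors for retinoic acid, oxysterols (LXR), fatty acids (PPAR) and vitamin D. In the knockouts Cre recombinase under the blood-specific Vav1 promoter was combined with floxed alleles of Rxra and Rxrb. Batch 1 holds 3 libraries each of floxed control LT-HSC, knockout LT-HSC, floxed control MPP and knockout MPP. Batch 2 holds 3 libraries each of LT-HSC from Vav1-Cre controls, from animals labelled RXR knockout, and from RXR knockouts with the Myc allele. The control genotype thus changes with the batch. Values are deposited TPM, whose sums per library run from 691094 to 918942, and the read depth behind them is unknown. A gene identifier without a symbol, ENSMUSG00000089855, alone took 10.6% to 51.8% of the TPM scale, most in LT-HSC floxed control 2.

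The targeted genes were looked at first, as a check of the labels. Rxra (ENSMUSG00000015846, mm10 chromosome 2, 27676445 to 27763319) can show a deletion in its TPM only as far as the removed part lowers the whole. In batch 1 LT-HSC it stood at 3.14 ± 0.251 TPM (SD, n = 3) in knockouts and at 3.80 ± 1.40 TPM (SD, n = 3) in floxed controls (exact two-sided permutation p = 0.6). In MPP the means were 2.02 and 2.12 TPM (exact p = 0.7), and in batch 2 they were 4.25 ± 3.11 TPM (SD, n = 3) in the libraries labelled knockout and 4.52 ± 0.362 TPM (SD, n = 3) in Cre controls (exact p = 0.7). Rxrb (ENSMUSG00000039656, chromosome 17, 34031812 to 34038403) was lower in every knockout library than in every control in MPP, with means of 11.3 and 17.6 TPM, and in batch 2, with 11.5 and 15.2 TPM, each at an exact p of 0.1, the smallest that 3 against 3 allows. In batch 1 LT-HSC its means were 10.6 and 12.2 TPM (exact p = 0.8).

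A splice junction shows the Rxra deletion more directly. The junction that skips an exon of Rxra (chromosome 2, 27741203 to 27748612) had a PSI of 0.938 in knockout LT-HSC 1, of 1 and 0.5 in knockout MPP 1 and 3, and no value in the other batch 1 knockouts. It was 0 in the controls except for 0.1 in LT-HSC floxed control 2. In the libraries labelled knockout of batch 2 it was 0, 0.0127 and 0, so the skipping junction did not exceed the control values there. In the Myc allele group it was 0.647, 0 and 1. The Myc allele was visible at Myc (ENSMUSG00000022346, chromosome 15, 61985341 to 61990361), where a junction from 61988278 to 61989346 had a PSI of 0.761, 1 and 0.736 in that group and of 0.976 to 0.999 in all other libraries. Myc stood at 91.4 ± 36.2 TPM (SD, n = 3) in the Myc allele group against 142 ± 1.45 TPM (SD, n = 3) in Cre controls (exact p = 0.1) and 128 ± 28.3 TPM (SD, n = 3) in the libraries labelled knockout (exact p = 0.3). Directions drawn from these libraries are worded below as those of libraries labelled knockout, and replicate 2 of the Myc allele group shares this limit.

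**Figure D1:**
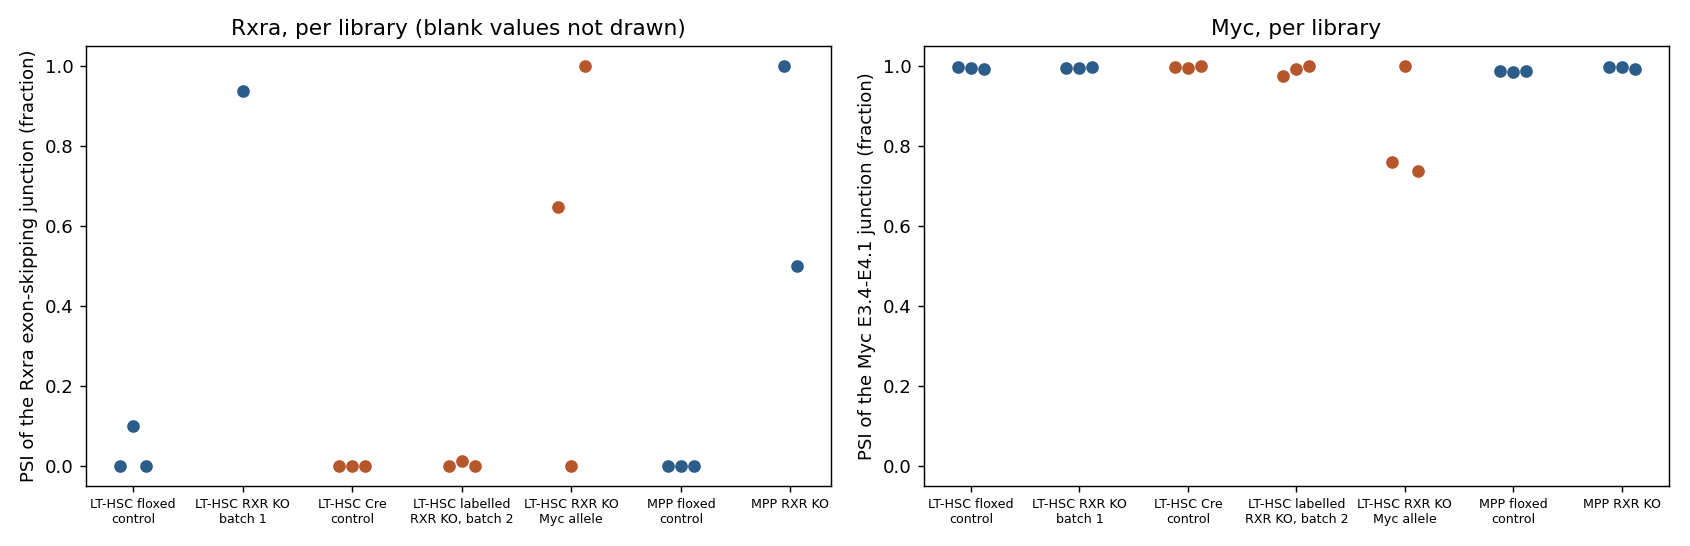
PSI (0 to 1) per library of the Rxra exon-skipping junction (left) and of a Myc junction (right), by group, with missing values not drawn. The skipping junction reached 0.5 or more in batch 1 knockouts with a value and stayed at 0.0127 or below in the batch 2 libraries labelled knockout.

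Floxed control MPP were compared with floxed control LT-HSC as a check of the sort and for the scale of a difference between cell types. Genes of cells that have begun to choose a lineage were higher in MPP. Dntt, which encodes the terminal transferase of lymphoid progenitors, Mpo, the granule enzyme of myeloid cells, and Cd48, a surface marker absent from stem cells, all rose. Slamf1, the stem cell marker CD150, the stem cell transglutaminase gene Tgm2 and the retinaldehyde dehydrogenase gene Aldh1a1 fell. Several genes of the retinoic acid pathway were higher in the stem cells. The B cell transcripts Igkc and Ighm, chosen after their values were seen, stood at 6734 ± 4441 and 1585 ± 921 TPM (SD, n = 3) in MPP. In LT-HSC they stood at 93.6 and 0.959 TPM. RNA of B cells may thus add to the differences between these cell types, which was not tested. Dntt (chromosome 19, 41029275 to 41059525) stood at 178 ± 36.8 TPM (SD, n = 3) in MPP and 0.288 ± 0.198 TPM (SD, n = 3) in LT-HSC, a log2 change of 7.11 (SE 0.20, limma with Benjamini-Hochberg adjusted p = 9.4e-12). Cd48 rose from 1.64 to 84.9 TPM, and Slamf1 fell from 11.8 to 0.354 TPM. Of the 40 LT-HSC genes tested, 28 fell and 1 rose over all genes, and 29 fell and 1 rose adjusted over the list alone, among them Vwf and Clca3a1. Of 23 lymphoid priming genes 20 rose by both adjustments, with Flt3 and Satb1 beside Dntt. Of 29 myeloid priming genes 24 rose, and 26 adjusted over the list alone, such as Irf8 and Plac8. Of 27 megakaryocyte and erythroid priming genes 21 fell and 1 rose, and 23 fell and 1 rose adjusted over the list alone, and 8 of 12 erythroid cell markers fell (10 adjusted over the list alone). Of 11 retinoic acid receptor targets 6 fell and 3 rose by both adjustments, with Tgm2, Rarb and Cyp26b1 among those that fell, and of 12 RXR partner receptors 4 fell and 1 rose over all genes (5 fell and 2 rose adjusted over the list alone). The inflammatory NF-kB response was higher in MPP, with 19 of 24 members up over all genes and 20 adjusted over the list alone. S phase and G2 and M phase lists were higher too, with 22 of 42 and 21 of 40 members up over all genes, and 30 and 29 adjusted over the list alone. These lists passed camera at adjusted p-values of 3.6e-34 (LT-HSC genes) to 8.4e-04 (RXR partner receptors), and none passed with an estimated correlation (adjusted p = 0.166 to 0.83). PPAR targets (adjusted p = 0.0223), Myc targets (0.0251), splicing factors (0.0275), B cell markers (0.00303), T and NK cell markers (0.00271), monocyte, macrophage and dendritic cell markers (0.00216) and neutrophil markers (0.0473) passed camera as well, and also not with an estimated correlation (adjusted p = 0.166 to 0.963). In all, 2305 genes rose and 834 fell of 14839 tested. The median of all genes was shifted by 0.26 in log2, and after rescaling 1667 rose and 1849 fell. The 3139 genes became 1784 without MPP floxed control 1 and 1834 without MPP floxed control 2.

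All 6 LT-HSC libraries labelled knockout were compared with all 6 LT-HSC controls, with batch as a term, to ask what stem cells without RXR express differently. The batch 2 libraries labelled knockout, whose skipping junction did not exceed the control values, are included here. Within batch 1 alone 6700 genes passed on deposited TPM and 698 after rescaling. Over both batches few genes passed, and their number depended on scale. Ivd, which encodes an enzyme of leucine breakdown, Matn4, a matrix protein gene that restrains stem cell proliferation under stress, and Vmp1, needed to form autophagosomes, were among the genes that rose. The retinoic acid hydroxylase gene Cyp26b1 was lower. Of 14492 genes tested 58 rose and 3 fell, and after rescaling 0 passed, with 2193 and 2817 genes at an unadjusted limma p under 0.05. Ivd stood at 49.0 ± 17.5 TPM (SD, n = 6) against 19.9 ± 5.73 TPM (SD, n = 6), a log2 change of 1.23 (SE 0.25, limma with Benjamini-Hochberg adjusted p = 0.0461, rescaled 0.0759). Matn4 rose by 1.40 (adjusted p = 0.0427, rescaled 0.0629), Morn3 by 1.10 (0.0427, rescaled 0.0629) and Vmp1 by 1.09 (0.0477, rescaled 0.0629). No gene at all passed without any 1 of the 3 floxed controls, of knockouts 2 and 3 or of Cre control 4. In place of 61 genes, 8 passed without Cre control 5, 106 without Cre control 6, 179 without knockout 1, 15 without 4, 150 without 5 and 387 without 6. The 3 genes that fell, chosen for naming after their values were seen, were Cyp26b1 (log2 change -1.34, adjusted p = 0.0477, rescaled 0.0771), Gimap3 (-1.14, adjusted p = 0.0427, rescaled 0.0629) and Gm13736 (-2.29, adjusted p = 0.0493, rescaled 0.0939). Gm13736 was higher in every Cre control than in any other LT-HSC library, floxed controls included. Rxra (log2 change -0.22, adjusted p = 0.85) and Rxrb (-0.26, adjusted p = 0.676) did not pass. Relative to the median of all genes, which lay at 0.14, 21 lists passed camera and none with an estimated correlation (adjusted p = 0.616 to 0.84). The inflammatory NF-kB response lay at -0.44 relative to that median (22 members, camera adjusted p = 5.0e-08, 0 members past the test over all genes and 1 lower adjusted over the list alone), immediate early genes at -0.44 (26 members, 2.7e-08), and erythroid cell markers at -0.59 (14 members, 5.4e-07). LXR targets lay at -0.27 (18 members, camera adjusted p = 0.00181). Neutrophil markers (0.00119), T and NK cell markers (0.0105) and the interferon response (3.9e-04) lay above it, and 12 of 45 interferon genes were higher adjusted over the list alone.

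Within batch 1, knockout LT-HSC were compared with floxed controls, which differ from them by Cre as well as by RXR. Relative to all other genes, erythroid markers and the NF-kB response lay lower and myeloid priming genes higher, though no list passed with an estimated correlation. Klf9, a nuclear receptor-induced repressor, Cd69, an early activation marker that holds cells in tissue, and Klf1 and Car1, regulator and enzyme of red cell precursors, fell. Prg2, the major basic protein gene of eosinophils, S100a8 and S100a9, the calprotectin genes of neutrophils, and the stem cell surface genes Clca3a1 and Neo1 rose. The alarm genes Nfkbia and Tnfaip3, which NF-kB switches on to limit itself, were lower.

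Klf9 (ENSMUSG00000033863, chromosome 19, 23141226 to 23168129) stood at 4.86 ± 0.695 TPM (SD, n = 3) against 15.4 ± 5.04 TPM (SD, n = 3), a log2 change of -1.45 (SE 0.23, limma with Benjamini-Hochberg adjusted p = 0.00244, rescaled -1.99 with 6.4e-04). Cd69 fell from 16.9 to 5.34 TPM (adjusted p = 0.00456) and Gda, a guanine deaminase gene, from 12.7 to 1.73 TPM (adjusted p = 0.00155). Car1 stood at 36.1 ± 39.6 TPM (SD, n = 3) in floxed controls and 4.26 TPM in knockouts, and Klf1 at 33.3 ± 31.1 against 7.39 TPM, so the control libraries varied widely, and Klf1 was lost without knockout 3 (adjusted p = 0.0558). Prg2 rose from 0.394 to 24.9 ± 13.7 TPM (SD, n = 3), a log2 change of 4.06 (SE 0.49, adjusted p = 7.2e-04, rescaled 0.00904). Clca3a1 rose by 2.26 (adjusted p = 2.6e-04, rescaled 0.00227), Neo1 by 1.96 (7.2e-04, rescaled 0.0167), Tgfbi, a matrix gene of monocytes, by 2.31 (2.2e-04, rescaled 0.00279) and the odorant receptor gene Olfr632 by 2.58 (2.1e-05, rescaled 2.4e-04). S100a8 stood at 261 ± 269 TPM (SD, n = 3), from 55.7 to 565 between libraries, against 22.2 ± 6.35 TPM (SD, n = 3), and its call (adjusted p = 0.00904) was lost on rescaling (0.0788), as was that of S100a9 (0.00722, rescaled 0.063). Sva (chromosome 6, 42038394 to 42042851), a secretory gland gene, stood at 13.8 ± 3.67 TPM (SD, n = 3) in knockouts and was listed at 0 in the 3 floxed controls. Of the 20 genes named by rule, 15 passed in every fit without 1 library. Mycn rose by 1.22 (adjusted p = 0.00492) and did not pass after rescaling (0.0888), and Myc did not pass (adjusted p = 0.287).

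Among the lists in LT-HSC of batch 1, 20 of 29 myeloid priming genes rose and none fell, by both adjustments, and 3 rose after rescaling (8 adjusted over the list alone), led by Hk3, Gfi1 and Plac8 (camera adjusted p = 0.0128, and 0.672 with an estimated correlation). Of 40 LT-HSC genes 26 rose and 1 fell, and 31 rose and 1 fell adjusted over the list alone, with Clca3a1, Neo1, Hoxb5 and Vwf in front, while 5 rose and 2 fell after rescaling (camera adjusted p = 0.00181, and 0.672 with an estimated correlation). Of 45 interferon genes 35 rose, and 38 adjusted over the list alone, with Oas2 and Oas3 first, and 5 rose and 1 fell after rescaling (camera adjusted p = 3.3e-04, and 0.672 with an estimated correlation). The inflammatory NF-kB list lay at -0.54 relative to the median of all genes (24 members, camera adjusted p = 7.2e-14, and 0.173 with an estimated correlation). In it 3 members fell and 2 rose over all genes, 2 fell and 2 rose adjusted over the list alone, and after rescaling 8 fell over all genes and 12 adjusted over the list alone. The log2 change was -1.03 for Tnfaip3 (adjusted p = 0.0101), -0.69 for Nfkbia (0.0164) and -0.48 for Nfkb2 (0.0306). Of 12 erythroid cell markers 6 fell and 1 rose by both adjustments, such as Hba-a1, and after rescaling 7 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 5.9e-15, and 0.173 with an estimated correlation), and of 27 megakaryocyte and erythroid priming genes 5 fell and 8 rose by both adjustments, while 8 fell and 2 rose after rescaling (camera adjusted p = 7.1e-09, and 0.649 with an estimated correlation). LXR targets were lower relative to all genes (17 members, camera adjusted p = 1.7e-04, and 0.649 with an estimated correlation). Mylip, the LXR-induced ligase of the LDL receptor, fell by 0.96 (adjusted p = 0.00843), and after rescaling Fasn and Arl4c passed as well (0.0167 and 0.0173). Immediate early genes, Myc targets, S phase, G2 and M phase, translation factors, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein response and splicing factors lay below the median of all genes, at camera adjusted p-values of 7.2e-14 to 0.0145, and endothelial and stromal cell markers above it (0.0429), none of them with an estimated correlation (lowest adjusted p = 0.392). Retinoic acid receptor targets (adjusted p = 0.0789), PPAR targets (0.137), RXR partner receptors (0.11), neutrophil markers (0.0542), monocyte, macrophage and dendritic cell markers (0.11), markers of B cells (0.232), of T and NK cells (0.344) and of mast cells, basophils and eosinophils (0.785), lymphoid priming (0.274), glycolysis (0.82), p53 targets (0.64), lysosome and autophagy (0.742) and sex-linked genes (0.731) did not pass. Neutrophil markers lay 1.16 above the median all the same, with 8 of 11 members up over all genes, and passed after rescaling with 0 members up over all genes and 6 adjusted over the list alone (camera adjusted p = 6.7e-05, and 0.375 with an estimated correlation).

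The number of genes past the test in LT-HSC of batch 1 hung on the scale. On deposited TPM 6614 rose and 86 fell of 14839, and the median of all genes was higher by 0.52 in log2. After rescaling 377 rose and 321 fell, and with quantile scaling 334 and 349. Knockout libraries also listed more genes at 1 TPM or more, 13923 to 14870 against 12455 to 13249 in floxed controls. In place of 6700 genes, 3574 passed without floxed control 2, 2090 without knockout 2 and 1934 without knockout 3. The total counts in this comparison are therefore given on both scales.

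**Figure D2:**
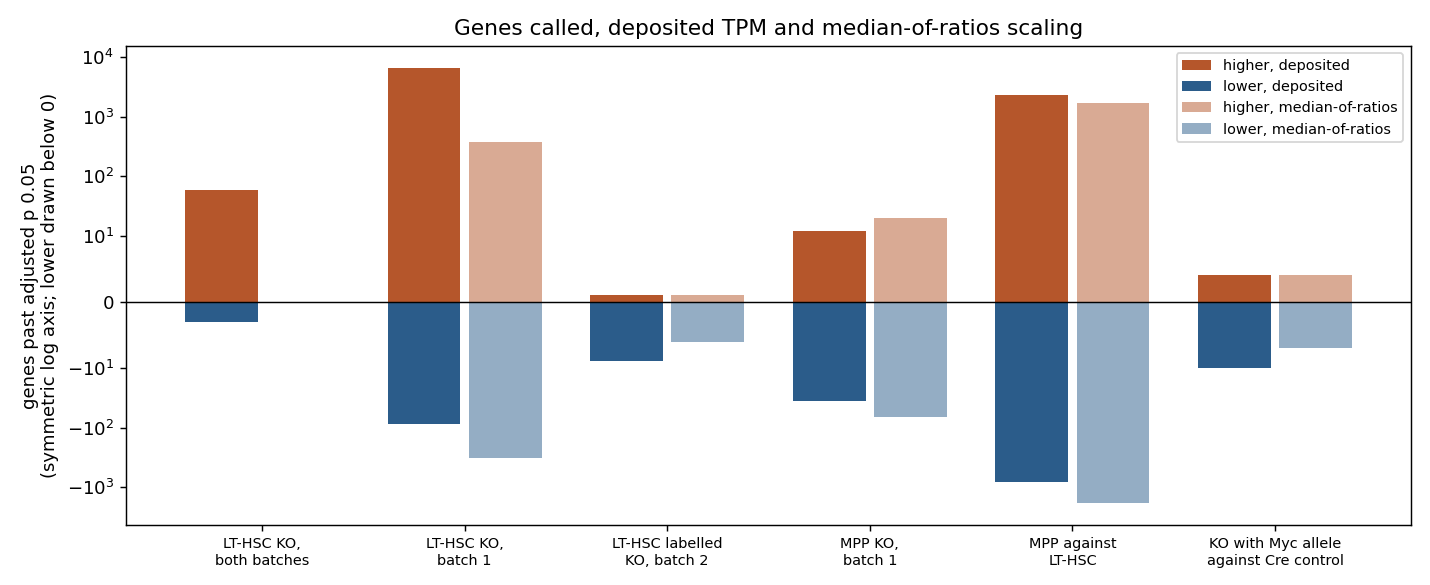
Number of genes higher and lower past an adjusted p of 0.05 in 6 comparisons, on deposited TPM and after median-of-ratios rescaling, on a symmetric log axis. In LT-HSC of batch 1, rescaling took the count from 6614 higher and 86 lower to 377 and 321.

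Within batch 2, the libraries labelled knockout were compared with Cre controls, which carry Cre without floxed alleles. Few genes differed, and none of them passed in the same direction in batch 1. The chemokine gene Ccl3, made by activated myeloid cells, was lower in the libraries labelled knockout. The ribosomal protein copies Rps3a2 and Rps3a3 and the enolase copy Eno1b passed as well, and the other 6 genes were predicted genes named Gm with a number. Klf9 and Nfkbia stood near their control levels here. Of 13445 genes tested 1 rose and 9 fell, and without Cre control 4, 5 or 6 the 10 became 6, 5 and 5. Rps3a3 (chromosome 13, 108670580 to 108671443) stood at 1.06 ± 0.293 TPM (SD, n = 3) against 484 ± 277 TPM (SD, n = 3) in Cre controls, a log2 change of -7.72 (SE 0.38, limma with Benjamini-Hochberg adjusted p = 2.3e-07). It is nearly identical in sequence to other genes of its family, so these values are uncertain, as are those of Rps3a2 and Eno1b. Ccl3 fell by 2.74 (adjusted p = 0.021), to 1.83 from 16.5 TPM, and did not pass after rescaling (0.164) or without any 1 of the Cre controls or of libraries labelled knockout 4 and 6 (0.0731 to 0.209). The gene that rose, Gm13443, chosen after its values were seen, was listed at 0 in the Cre controls. Of the genes named as higher, Rdh16 was first (adjusted p = 0.705). Klf9 had means of 13.1 and 15.0 TPM. On deposited TPM the median of all genes lay at -0.25, and 1 gene rose and 6 fell after rescaling. Translation factors (camera adjusted p = 7.1e-05), ribosomal proteins (0.0286), G2 and M phase (0.0142), myeloid priming (0.0142) and sex-linked genes (0.0142) lay below the median of all genes and the interferon response above it (0.0284), none with an estimated correlation (adjusted p = 0.9). None of their members passed over all genes, and 5 myeloid priming and 3 sex-linked genes were lower adjusted over the list alone. The Y-linked gene Ddx3y stood at 4.82 ± 5.34 TPM (SD, n = 3) in Cre controls and at 0.0704 ± 0.0918 TPM (SD, n = 3) in the libraries labelled knockout, so transcripts of male cells differed between these pools.

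Whether the LT-HSC effect differed between the batches was tested as an interaction. Prg2 and several myeloid priming genes that rose in batch 1 did not rise among the batch 2 libraries labelled knockout. Mpo and Elane, granule genes of neutrophil precursors, Prg2 and Tgfbi had a lower effect in batch 2. So had Rps3a3 and Rps3a2 (limma with Benjamini-Hochberg adjusted p = 4.4e-08 each) and Eno1b (1.1e-04), which among LT-HSC were high in the Cre controls alone. The Y-linked gene Eif2s3y did as well (0.0312). The control genotype and the sex of the pools thus enter this difference too. Of 14492 genes 180 had a lower effect in batch 2 and 4 a higher one, and 10 and 8 after rescaling, with the median of all genes at -0.73 on deposited TPM. The 184 became 2355, 18 and 94 without floxed control 1, 2 and 3, 53, 45 and 73 without Cre control 4, 5 and 6, and 765, 30, 23, 101 and 5548 without knockout 1, 2, 3, 5 and 6. The difference for Prg2 was -4.68 in log2 (limma with Benjamini-Hochberg adjusted p = 2.4e-04, rescaled 0.0165), for Mpo -4.72 (0.00998, rescaled 0.14), for Elane -4.03 (0.0079, rescaled 0.0979) and for Tgfbi -2.79 (0.00797, rescaled 0.078). Mpo was lost without LT-HSC floxed control 2 (adjusted p = 0.0537). Klf9 had a difference of 1.22 (adjusted p = 0.0637), which passed after rescaling (1.97, 0.00838). The 4 genes with a higher effect, chosen after their values were seen, were Gm13443, Gm15344, Gm17024 and Gm8810. Of 25 myeloid priming genes, 8 had a lower effect over all genes and 18 adjusted over the list alone (camera adjusted p = 4.0e-06, and at least 0.769 with an estimated correlation). Erythroid cell markers had a higher effect in batch 2, by 1.30 relative to all genes (camera adjusted p = 7.9e-10), as had the inflammatory NF-kB response (0.00328) and immediate early genes (9.9e-04), and LT-HSC genes a lower one (1.9e-04), none with an estimated correlation (adjusted p = 0.769 to 0.976).

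The genes that passed in LT-HSC of batch 1 were then followed as lists in the 9 libraries of batch 2, with which they share no library. In the libraries labelled knockout against Cre controls, the list of genes higher in batch 1 (5920 tested) lay 0.07 above the median of all genes (camera p = 2.6e-04, and 0.286 with an estimated correlation) and the list of lower ones (78 tested) 0.05 above it (camera p = 0.709). The lower list turned to -0.05, -0.0096 and -0.126 without Cre control 5 and libraries labelled knockout 4 and 5. Without 6 it rose to 0.292 and passed camera (p = 0.00192), but not with an estimated correlation (0.0626). With the lists and the fit rescaled, 322 higher genes lay 0.336 above the median (camera p = 1.5e-09, and 0.107 with an estimated correlation) and 314 lower ones at -0.037 (camera p = 0.136). In the Myc allele group against the libraries labelled knockout, the lower list lay at -0.44 relative to the median (camera p = 8.4e-09, and 0.00553 with an estimated correlation, and 0.0803 with it without library labelled knockout 5 and 0.133 without Myc allele 1) and the higher list 0.07 above it (0.00186, and 0.358 with an estimated correlation), which did not pass camera without Myc allele 2 (0.0413 above) or 3 (0.037 above). Rescaled, the lower list lay at -0.145 (camera p = 2.9e-04, and 0.0512 with an estimated correlation) and the higher list 0.219 above the median (2.3e-04, and 0.292 with an estimated correlation). Against Cre controls, a contrast added after the data were seen, the Myc allele group had the lower list at -0.51 relative to the median (camera p = 3.2e-05, and 0.0225 with an estimated correlation) and the higher list 0.13 above it (2.2e-08, and 0.123 with an estimated correlation). Without Myc allele 1 the lower list lay at -0.443 there and did not pass camera. Rescaled, the higher list lay 0.582 above the median (camera p = 1.9e-15, and 0.047 with an estimated correlation) and the lower list at -0.22 (1.6e-05, and 0.0276 with an estimated correlation). Klf9 stood at 10.8 ± 3.38 TPM (SD, n = 3) in the Myc allele group and at 13.1 ± 4.15 TPM (SD, n = 3) in the libraries labelled knockout. Its values overlapped between these groups, so this gene alone shows no shift.

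In MPP, knockouts were compared with floxed controls of batch 1 to ask whether RXR also acts in progenitors. Genes of the inflammatory NF-kB response were lower in knockout MPP, which differ from these controls by Cre as well as by RXR. B cell transcripts, chosen after their values were seen, had lower means too. Ighm stood at 407 ± 478 TPM (SD, n = 3) against 1585 ± 921 TPM (SD, n = 3), and Igkc at 2356 against 6734 TPM. Whether RNA of B cells adds to the NF-kB difference was not tested. The NF-kB inhibitors Nfkbia, Nfkbie and Tnfaip3, the subunit genes Relb and Nfkb2, the activation marker Cd83 and the chemokine gene Cxcl2 all fell. The orphan nuclear receptor gene Nr4a3, the early activation marker Cd69 and the stress-induced Maff fell with them. Selp, the adhesion molecule P-selectin, and the monocyte genes Ccr2 and Ms4a6c rose.

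Of 24 inflammatory NF-kB genes 9 fell and none rose over all genes, and 18 fell adjusted over the list alone. The list lay at -1.03 relative to the median of all genes (camera adjusted p = 6.5e-43) and passed with an estimated correlation (adjusted p = 0.00906) and with fry (0.00173). Nfkbia (ENSMUSG00000021025, chromosome 12, 55489409 to 55492647) stood at 26.8 ± 2.83 TPM (SD, n = 3) against 85.4 ± 13.1 TPM (SD, n = 3), a log2 change of -1.63 (SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.00339). The log2 change was -1.78 for Cd83 (adjusted p = 5.5e-04), -1.27 for Nfkbie (0.00488) and -2.05 for Cxcl2 (0.00488), which fell from 86.9 to 21.3 TPM. Nr4a3 stood at 4.81 ± 2.32 TPM (SD, n = 3) against 24.4 ± 5.59 TPM (SD, n = 3), a log2 change of -2.18 (SE 0.30, adjusted p = 0.00488). Cd69 fell by 1.80 (adjusted p = 0.00877) and was lost without floxed control 2 (0.0506) or knockout 3 (0.0792). Tnfaip3 fell by 1.47 (adjusted p = 0.0286) and was lost without floxed control 1 (0.123), floxed control 2 (0.169), knockout 1 (0.0993) or knockout 3 (0.191). Selp rose by 1.62 (SE 0.25, adjusted p = 0.00758), to 52.5 from 16.3 TPM, and was lost without floxed control 2 (0.0506) or knockout 3 (0.0692). Sva stood at 11.1 ± 2.06 TPM (SD, n = 3) against 0.0546 ± 0.0946 TPM (SD, n = 3), a log2 change of 3.51 (SE 0.21, adjusted p = 5.8e-07). Of the 18 genes named by rule, 7 passed in every fit without 1 library, namely Sva, Nr4a3, Cxcl2, Nfkbia, Art2a-ps, Arl4c and Sytl3. In all, 12 genes rose and 36 fell of 14839, and 20 and 66 after rescaling. The 48 became 17 without floxed control 1, 14 without floxed control 2, 27 without knockout 2 and 17 without knockout 3.

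Other lists moved in MPP without passing at an estimated correlation. Immediate early genes lay at -0.60 relative to the median (26 members, 0 past the test over all genes and 10 lower adjusted over the list alone, camera adjusted p = 3.4e-20, and 0.168 with an estimated correlation). Myeloid priming lay 0.58 above it (29 members, 0 past the test over all genes and 13 higher adjusted over the list alone, such as F13a1 and Ms4a3, camera adjusted p = 8.5e-14, and 0.268 with an estimated correlation). Neutrophil markers lay 1.80 above it (11 members, 0 past the test over all genes and 7 higher adjusted over the list alone, camera adjusted p = 1.1e-12, and 0.268 with an estimated correlation), with S100a8 at 127 ± 109 TPM (SD, n = 3) against 8.40 ± 5.56 TPM (SD, n = 3). Of monocyte, macrophage and dendritic cell markers, Ccr2 and Ms4a6c rose and 4 of 10 adjusted over the list alone (camera adjusted p = 0.00723, and 0.437 with an estimated correlation), and of mast cell, basophil and eosinophil markers Fcer1a rose and 4 of 9 adjusted over the list alone (8.7e-05, and 0.168 with an estimated correlation). Of 17 LXR targets Arl4c and Mylip fell, and 3 adjusted over the list alone (0.00763, and 0.653 with an estimated correlation). Cholesterol synthesis (0.0291), the unfolded protein response (0.0479) and sex-linked genes (0.0291) were lower by camera, also not with an estimated correlation (adjusted p = 0.437 to 0.925). The remaining lists did not pass (camera adjusted p = 0.0537 to 0.989). The immunoglobulin transcript Igkc, chosen after its values were seen, stood at 6734 ± 4441 TPM (SD, n = 3) in floxed control MPP and 2356 ± 2384 TPM (SD, n = 3) in knockout MPP, so the share of B cell transcripts also varied between these libraries.

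**Figure D3:**
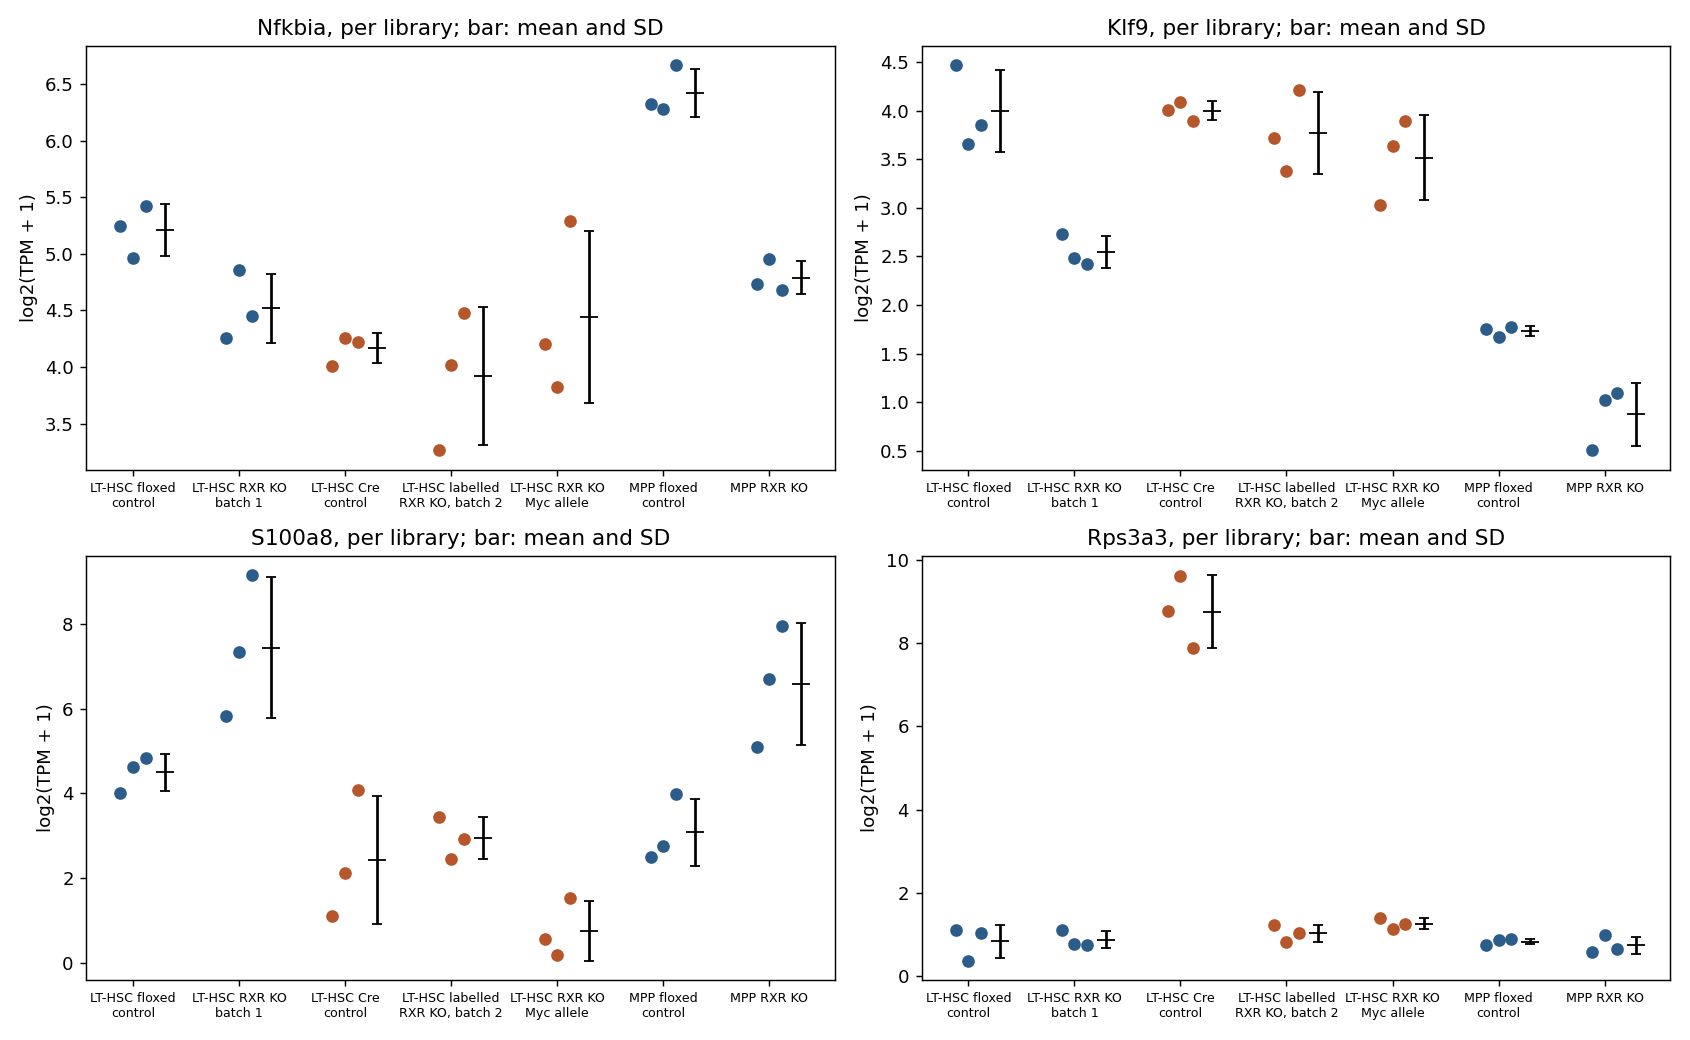
log2(TPM + 1) per library of Nfkbia, Klf9, S100a8 and Rps3a3 in the 7 groups, with batch 1 in blue, batch 2 in orange, and bars for the mean ± SD of 3 libraries. Nfkbia is lower in knockout MPP, Klf9 in knockout LT-HSC of batch 1, and Rps3a3 is high in the Cre controls of batch 2.

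The LT-HSC and MPP effects of batch 1 were set side by side. Sva, listed at 0 in all batch 2 libraries, was higher in batch 1 knockouts. Its rise and lower Nfkbia, Tnfaip3, Cd69 and Mylip were common to both cell types. After rescaling, 10 genes were higher and 32 lower in both, against 0.508 and 1.43 for independent lists, and the fold changes correlated across genes with a Pearson r of 0.271, where genes are not independent replicates. Both cell types carry the same pool names in the labels, so differences between pools may add to this overlap and to r. The difference between the cell types, tested as an interaction, called 1 gene with a higher and 11 with a lower effect in MPP, and 1 and 3 after rescaling, with the median of all genes at -0.45 on deposited TPM. With the pools as a block it called 1342 genes against 12. The 12 became 847, 2 and 38 without LT-HSC floxed control 1, 2 and 3, 1905, 2 and 3 without LT-HSC knockout 1, 2 and 3, 4, 2 and 5 without MPP floxed control 1, 2 and 3, and 6 and 2 without MPP knockout 2 and 3. The gene with the higher effect, chosen after its values were seen, was Gda (log2 difference 3.07, limma with Benjamini-Hochberg adjusted p = 0.0251, rescaled 0.0344). Among the lower, Lncpint, a p53-induced long RNA, had a difference of -1.76 (adjusted p = 0.0463, rescaled 0.155) and Bach2os, an antisense gene, one of -2.57 (0.0463, rescaled 0.229). Of 12 fits without 1 library, Bach2os was lost in 7 and Lncpint in 9, at adjusted p-values up to 0.177. In floxed controls 19 members of the inflammatory NF-kB list were higher in MPP than in LT-HSC, where Cd83 stood at 0.177 TPM and could hardly fall. The lower starting level in LT-HSC may thus add to the difference for this list, which was not tested. The inflammatory NF-kB list fell further in MPP than in LT-HSC, with a difference of -0.47 relative to all genes (camera adjusted p = 3.7e-05, 1 member over all genes, 8 with the block, and 14 adjusted over the list alone), and not with an estimated correlation (adjusted p = 0.698). Erythroid cell markers (3.1e-10), megakaryocyte and erythroid priming (3.1e-10), Myc targets (4.0e-09), oxidative phosphorylation (4.8e-09), S phase (2.7e-08), translation factors (6.9e-07), ribosome biogenesis (1.5e-04), neutrophil markers (3.0e-04), G2 and M phase (7.7e-04), ribosomal proteins (0.00104), mast cell, basophil and eosinophil markers (0.00434), myeloid priming (0.00623) and PPAR targets (0.0357) had a higher effect in MPP and LT-HSC genes (0.00187) and the interferon response (0.0256, with the block 0.105) a lower one, none with an estimated correlation (adjusted p = 0.698 to 0.869). Klf1 had a difference of 1.84, which passed only with the block (adjusted p = 0.131, and 0.0482 with the block).

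The Myc allele group was compared within batch 2 to ask what removing the allele adds to the RXR knockout. By the skipping junction Rxra deletion differs between these groups as well, and Myc allele 2 showed neither deletion, so no difference below can be assigned to the Myc allele alone. No gene passed against the libraries labelled knockout. Olfr632 was first among the higher genes and Morn3 among the lower. Against Cre controls, Olfr632 and the histone gene Hist1h4m rose, and Ccl3 and the X-linked Xlr4a fell. In the contrast with the libraries labelled knockout limma with Benjamini-Hochberg adjustment called 0 of 13445 genes on each scale, with 547 at an unadjusted p under 0.05 on deposited TPM and 746 after rescaling. Without Myc allele 1 it called 3 genes and without Myc allele 2 it called 1. Olfr632 had a log2 change of 2.10 (adjusted p = 0.57), Morn3 one of -1.66 (0.654) and Myc one of -0.54 (1). By camera the RXR partner receptors (adjusted p = 0.00135), LT-HSC genes (0.0127), the inflammatory NF-kB response (0.0453), immediate early genes (0.011) and sex-linked genes (0.0132) were higher than other genes. Oxidative phosphorylation (0.00617), S phase (0.00276), G2 and M phase (0.00276), megakaryocyte and erythroid priming (1.0e-04) and the interferon response (1.3e-05) were lower, no list passed with an estimated correlation (adjusted p = 0.905), and 0 members of these lists passed by either adjustment. Myc targets did not pass (adjusted p = 0.0964).

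Against Cre controls 4 genes rose and 10 fell in the Myc allele group, and 4 and 7 after rescaling. The 14 became 7, 6 and 5 without Cre control 4, 5 and 6, and 973 without Myc allele 1. Olfr632 stood at 12.9 ± 4.57 TPM (SD, n = 3) against 1.01 ± 0.392 TPM (SD, n = 3), a log2 change of 2.75 (SE 0.36, limma with Benjamini-Hochberg adjusted p = 0.00485), and was lost without Cre control 4 (0.0565) or 6 (0.0742). Hist1h4m was listed at 0 in the Cre controls and stood at 5.02 ± 2.27 TPM (SD, n = 3), and was lost without any 1 of those controls (adjusted p = 0.104 to 0.142). The log2 change was -2.98 for Ccl3 (adjusted p = 0.00764, rescaled 0.072), -2.47 for Xlr4a (0.0348, rescaled 0.174) and -7.49 for Rps3a3 (3.4e-07). Gm13443 and Gm8810, chosen after their values were seen, were the others that rose. By camera 13 lists lay below the median of all genes, G2 and M phase first (adjusted p = 4.3e-06), with Myc targets (0.0111), and T and NK cell markers above it (0.014), none with an estimated correlation (adjusted p = 0.788). Adjusted over the list alone, 6 of 22 myeloid priming genes and 4 of 27 megakaryocyte and erythroid priming genes were lower. This comparison shares its Cre controls with that of the libraries labelled knockout, where 1 higher and 9 lower genes were called in both. Their fold changes correlated across genes at r = 0.638, against 0.501 in 50 simulations of unchanged groups, with a covariance of 0.144 against 0.0866. The simulated groups shared their controls too, but each gene was drawn independently and without group differences. The simulations thus cannot say where the excess comes from.

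Splicing was compared where the design asked for it. In MPP the changes were nearly all of retained introns, among them introns of Nfkb2, of the autophagy kinase gene Ulk1 and of the clock gene Per2, which were spliced more fully in knockouts. Over both batches of LT-HSC a cassette exon of Ensa, a phosphatase regulator of mitosis, differed, and with the Myc allele an intron of the chaperone gene Hspa8. In MPP 50 events in 37 genes passed of 39312 tested, 49 of them of the intron retention type. The PSI of 25 events rose and that of 25 fell, and by the form that the examined junction measures, the spliced form rose in 34 of the 49, fell in 12 and was unclear in 3. The spliced form of Ahnak rose by 0.776 in PSI (limma with Benjamini-Hochberg adjusted p = 0.027), that of Nfkb2 (chromosome 19, 46310875 to 46311009) by 0.651 (0.0403), of Ulk1 by 0.627 (0.0422), of Per2 by 0.537 (0.0146) and of Pi4k2b by 0.483 (0.0435). In all LT-HSC 1 of 33282 events passed, at the cassette exon of Ensa (limma adjusted p = 0.022). Its examined junction (chromosome 3, 95628707 to 95631432) spans the end of the competing junction, so its PSI measures the form that skips the exon. That PSI was 0.965 ± 0.0602 (SD, n = 6) in libraries labelled knockout and 0.657 ± 0.0746 (SD, n = 6) in controls. Within batch 1, LT-HSC had as many events as MPP, 50 in 37 genes with 46 of the intron retention type, and within batch 2 they had 8, both counts outside the comparisons that the design asked for. For the Myc allele 4 of 25312 events passed, with Hspa8 at a PSI of 0.0851 against 0.927 (adjusted p = 0.0022) and a cassette exon of Gmfb at 0.44 against 0.00667 (0.039). With a logit of PSI the LT-HSC event and the 4 of the Myc allele no longer passed, and limma called 0 in both, while MPP had 84. Without 1 library the MPP events became 78 and 165 (floxed control 1 and 3) or 114 and 30 (knockout 1 and 2). The exon event count of LT-HSC became 0 without floxed control 1 or 2, Cre control 4 or 5, or knockout 2, 4 or 5, and 6 without knockout 6, and that of the Myc allele 42 without knockout 6, 306 without Myc allele 1 and 7 without Myc allele 2. Beside these, 3449, 2808 and 1506 events had an unadjusted p under 0.05.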

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

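The tests of what lay behind the 3 patterns weighed at the end of this part were chosen after the results were seen, as were the splits that keep the pools of animals, the rescaled splits and the count of splits that mix both strata, while the other splits of the samples were fixed earlier.

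In the 6 LT-HSC libraries labelled RXR knockout of both batches, 28 measures were tested for a library that stands far from the others, and 4 did, where chance would pick out about 1 in 20. The mitochondrial share of knockout 6 was 3.08% against 4.90% in the next library (gap 0.681 of the range). S100a8 in knockout 3 was 565 TPM against 162 (0.719), Cd151 in knockout 4 was 23 TPM against 11 (0.77), and Mycn in knockout 6 was 64.6 TPM against 33.2 (0.703). The last 2 genes thus have means in this group that rest partly on 1 library.

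The knockout effect in LT-HSC differed between the batches in 184 genes, 9 lists by camera and 36 splicing events, by a test of the difference itself. Of 100 splits that keep the batches balanced, 2 gave as many genes, the real one included. The highest other split, with 468, kept the real groups of batch 1 and so holds their knockout effect. The other splits break up the knockout effect within a batch, so they ask whether there is any effect. They cannot decide whether it differs between the batches, and chance stays open for the 184 genes. After rescaling the difference was 18 genes, which 1 of 100 splits gave, the highest other being 10, and 19 lists, which 8 of 100 gave, up to 23. For the lists on deposited TPM 77 of 100 splits gave as many as the 9, up to 20, so chance cannot be excluded. Between MPP and LT-HSC the effect differed in 12 genes, 16 lists by camera and 18 splicing events. There 6 of 100 splits gave as many genes, up to 3423, a share that leaves chance open. The 5 others all kept the real groups of LT-HSC or of MPP, so that they hold the knockout effect itself. The 77 splits that mixed both gave 1 gene at most. These break up the knockout effect in both cell types, so they too cannot decide whether it differs. For the lists 39 of 100 splits gave as many, up to 23, and 24 of the 77, so chance cannot be excluded. Rescaled, the difference was 4 genes (as many in 2 of 100 splits, highest other 694) and 16 lists (26 of 100, highest other 22), and with the pools of animals as a block 1342 genes passed. Genotype has 10 splits over the 6 pools, too few for a share under 0.05. With the block, the real one gave 1342 genes (highest other 4) and 15 lists (highest other 18).

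For the comparisons themselves, 1 of 100 splits of the 12 LT-HSC libraries gave as many genes as the real 61, the highest other being 2. Chance can thus be excluded for that count on deposited TPM only, since after rescaling 0 genes passed. For lists, 1 of 100 splits gave as many as the real 21. Another split gave 20, and 0 lists passed with an estimated correlation, so no conclusion is drawn from the count of lists. For the splicing event 6 of 100 splits gave as many as the real 1, up to 3, so chance cannot be excluded. The designs of 3 against 3 libraries have 10 splits, too few for a share under 0.05. There, 1 of 10 splits gave as many genes as the real one in LT-HSC of batch 1 (6700, highest other 2), in LT-HSC of batch 2 (10, highest other 0), in MPP (48, highest other 3), between cell types (3139, highest other 0, and with the pools as a block and swaps within pools 4426, highest other 0) and for the Myc allele group against Cre controls (14, highest other 0). For the Myc allele against the libraries labelled knockout, where limma with Benjamini-Hochberg adjustment called 0 genes and 547 had an unadjusted p under 0.05, all 10 splits gave as many, and 1 that put libraries labelled knockout 4 and 6 with Myc allele library 1 gave 300, which points to a structure of the samples. Lists were as many in 1 of 10 splits in LT-HSC of batch 1 (19, highest other 17), in 8 in batch 2 (6, highest other 11), in 7 in MPP (10, highest other 17), in 4 between cell types (17, highest other 19), in 5 for the Myc allele (10, highest other 12) and in 2 for the Myc allele group against Cre controls (14, highest other 15). Splicing events were as many in 1 of 10 splits in MPP (50, highest other 34) and in 4 for the Myc allele (4, highest other 7).

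The first pattern is that genes changed in knockout LT-HSC of batch 1 moved in part or not at all in the batch 2 libraries labelled knockout, by 0.336 relative to all genes for the higher list and by -0.037 for the lower one after rescaling. Lower depth or quality in batch 2 cannot be told apart from the rest. The rescaled higher list moved 1.733 times as far in the Myc allele group, sequenced in the same batch with more missing splicing values, as in the libraries labelled knockout, but these groups did not differ in it with an estimated correlation (p = 0.292). Missing deletion or a wrong label remains open and is consistent with the highest share of the Rxra exon-skipping junction in these 3 libraries, 0.0127, which stayed below the 0.1 of a control. Some values run the way of the labels, with Rxrb at 11.5 TPM against 15.2 TPM in Cre controls and lower in every library (exact p = 0.1), and Cyp26b1 at 0.978 TPM against 2.84 TPM (limma with Benjamini-Hochberg adjusted p = 0.705). But Rxrb fell by 0.376 in log2 where the median of all genes lay at -0.252, so part of its fall is shared with all genes. Klf9 stood at 13.1 TPM, near the 15.0 TPM of Cre controls, against 4.86 TPM in batch 1 knockouts. Olfr632 stood at 2.23 TPM, against 13.2 TPM in batch 1 knockouts and 12.9 TPM in the Myc allele group. The control genotype cannot be told apart from a missing deletion or a wrong label. The rescaled list lower in batch 1 lay at -0.1451 between the Myc allele group and the libraries labelled knockout. That contrast is without controls, but the Myc allele differs in it as well. Differences in sex or age of the pools stay open and were not tested as causes.

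The second pattern is the set of 10 genes called in batch 2 against Cre controls, with Ccl3, the copies Rps3a2, Rps3a3 and Eno1b and 6 predicted genes. Loss of RXR is argued against, since 9 of the 10 also separate the Cre controls from the floxed controls, which have RXR. A strain or passenger variant of the Cre controls is a candidate explanation, with 9 of 10 genes setting the 3 Cre controls apart from each of the 12 other LT-HSC libraries. Ccl3, the exception, had a lowest value of 12.9 TPM in Cre controls and reached 20.2 TPM in the others. Reads shared between near-identical copies may add to the difference, and strain was not stated for single libraries.

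The third pattern is that neutrophil markers lay higher in batch 1 knockout LT-HSC. Markers of other cell types did not all rise, as erythroid cell markers lay at -1.11 relative to all genes after rescaling, with 7 of 12 members lower over all genes. This cannot decide on a lower share of the sorted cells, because added RNA of 1 cell type need not bring erythroid RNA. The erythroid genes Car1 and Klf1 also varied widely between the floxed controls. The B cell transcript Igkc goes the other way from the erythroid markers, at 545 ± 271 TPM (SD, n = 3) against 93.6 ± 103 TPM (SD, n = 3) (limma with Benjamini-Hochberg adjusted p = 0.0227, rescaled 0.129), so RNA of B cells stays open as well. RNA from neutrophils cannot be told apart from expression by the sorted cells, since the fixed neutrophil list, 1.27 above the median of all genes after rescaling, is the pattern itself, with S100a8 at 55.7, 162 and 565 TPM and Camp at 6.72, 20.1 and 65.65 TPM in knockouts 1, 2 and 3. Both means rest largely on knockout 3, and Camp did not pass without knockout 3 (adjusted p = 0.0689), knockout 2 (0.0512) or floxed control 2 (0.0574). Knockout MPP 1, 2 and 3, which carry the same pool names, had S100a8 at 32.9, 102 and 247 TPM. Its order over the knockout pools was thus the same in both cell types. The sort took lineage-negative cells, which would remove neutrophils. A change of the knockout stem cells themselves, with loss of RXR as the biological difference that the design gives, stays open beside it and was not tested separately.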

How the results depend on the processing

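Several alternatives were chosen after the data were seen, namely the fits without the 3 batch 2 libraries labelled knockout, the median-of-ratios fits without LT-HSC floxed control 2 and the 100-gene lists on that scale. Read depth is unknown, so what it limits cannot be computed, and with 3 libraries a group the fits found most changes of 2 in log2 and few of 1 in batch 2. For every change below the cause was not tested, unless a smaller set of libraries or genes makes it.

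The 61 genes of all LT-HSC became 0 with a pseudocount of 0.1, no filter, median-of-ratios or quantile scaling, no batch term, or median-of-ratios without floxed control 2. They became 115 at 5 TPM, 523 with array weights, 16 with all 21 libraries in the fit and 4996 without the 3 libraries labelled knockout. Leaving out 1 library gave 0 to 387 (0 without floxed control 1, 2 or 3, Cre control 4 or knockout 2 or 3, 8 without Cre control 5, 106 without Cre control 6, 179 without knockout 1, 15 without 4, 150 without 5, 387 without 6). The 6700 genes of LT-HSC in batch 1 became 698 and 683 with median-of-ratios and quantile scaling, 3602 with only the 6 libraries compared, 345 with median-of-ratios without floxed control 2, and 1934 to 8246 without 1 library (3574 without floxed control 2, 2090 without knockout 2, 1934 without 3). The 10 genes of batch 2 became 18 with no filter, 3793 with array weights and 5 to 9 without 1 library (6 without Cre control 4, 5 without 5 or 6). The 48 genes of MPP became 86 with median-of-ratios scaling, 1045 with array weights, 134 with only the 6 libraries compared, and 14 to 50 without 1 library (17 without floxed control 1, 14 without 2, 27 without knockout 2, 17 without 3). The 3139 genes between cell types became 1784 to 3816 without 1 library (1784 without MPP floxed control 1, 1834 without 2). For the Myc allele 0 became 0 to 3 without 1 library (3 without Myc allele 1, 1 without 2), and against Cre controls 14 became 5 to 973 (7, 6 and 5 without Cre control 4, 5 and 6, 973 without Myc allele 1).

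The 184 genes that differed between batches became 63 with a pseudocount of 0.1, 62 with no filter, 967 at 5 TPM, 18 with either scaling, 6530 with array weights, 14 with median-of-ratios without floxed control 2, and 18 to 5548 without 1 library (2355, 18 and 94 without floxed control 1, 2 and 3, 53, 45 and 73 without Cre control 4, 5 and 6, and 765, 30, 23, 101 and 5548 without knockout 1, 2, 3, 5 and 6). The 12 genes that differed between MPP and LT-HSC became 3 with a pseudocount of 0.1, 22 with no filter, 1 at 5 TPM, 4 and 3 with median-of-ratios and quantile scaling, 1905 with array weights, 0 with median-of-ratios without floxed control 2 (limma), and 2 to 1905 without 1 library (847, 2 and 38 without LT-HSC floxed control 1, 2 and 3, 1905, 2 and 3 without LT-HSC knockout 1, 2 and 3, 4, 2 and 5 without MPP floxed control 1, 2 and 3, 6 and 2 without MPP knockout 2 and 3).

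With the replicate number as a block, counts became 298 for all LT-HSC, 1832 and 54 in batches 1 and 2, 167 in MPP, 1105 between batches, 1342 between MPP and LT-HSC, and 0 splicing events in LT-HSC and in MPP. Knockout and control libraries share only a number (correlations of deviations -0.117 to 0.342 in LT-HSC of batch 1, -0.176 to -0.0066 in batch 2, -0.0365 to 0.212 in MPP), and not every library correlated best with its own number. Only the values between cell types are paired, by the animal or pool names in the labels, although there too not every library correlated best with its own number. In these, 4426 genes passed against 3139 in controls, where Rxra newly passed (0.0439 against 0.0579). Camera passed 17 lists with and without the block in controls and 15 against 16 for the difference, where the interferon response was lost (0.105) and Klf1 newly passed (0.0482), and fry passed 12 against 13 and 5 against 1. Members past the test rose from 8 to 14 for Myc targets and from 4 to 13 for splicing factors in controls, and from 1 to 8 for the inflammatory NF-kB response and 0 to 14 for LT-HSC genes in the difference. The block changed no other camera call of a list and no other call of a gene named between cell types. By fry, G2 and M phase was lost in controls (adjusted p = 0.0319 without and 0.0842 with the block). Newly passing by fry in the difference were RXR partner receptors (0.029), T and NK cell markers (0.0214) and endothelial and stromal cell markers (0.029). Monocyte, macrophage and dendritic cell markers newly passed there too (0.0416).

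With an estimated correlation 0 lists passed in every comparison except MPP, with 1. With fry 13 passed between cell types, 11 in LT-HSC of batch 1, 5 between batches, 1 in MPP, 1 between MPP and LT-HSC, and 0 in all LT-HSC, batch 2 and both Myc allele comparisons. Median-of-ratios scaling gave 19 lists between batches against 9. The list lower in batch 1 lay at 0.05 in the batch 2 libraries labelled knockout. It reversed to -0.037 with median-of-ratios scaling and to -0.017 with that scaling and 100 genes. It also reversed to -0.05, -0.0096 and -0.126 without Cre control 5 and libraries labelled knockout 4 and 5. Without 6 it rose to 0.292 and passed camera, but not with an estimated correlation (p = 0.0626), so the range was -0.126 to 0.292. The higher list, at 0.074, ranged from 0.0637 to 0.0734 without 1 library and became 0.29 with 100 genes, 0.336 with median-of-ratios scaling and 0.214 with both. For the Myc allele the higher list, at 0.065, ranged from 0.037 to 0.115 without 1 library, did not pass without Myc allele 2 (0.0413) or 3 (0.037), and became 0.277 with 100 genes, 0.219 with median-of-ratios scaling and 0.25 with both. The lower list, at -0.437, ranged from -0.656 to -0.291 without 1 library and became -0.662 with a pseudocount of 0.1, -0.328 with 100 genes, -0.145 with median-of-ratios scaling and -0.243 with both.

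The splicing event of LT-HSC became 0 with a logit of PSI and 0 to 6 without 1 library (0 without floxed control 1 or 2, Cre control 4 or 5, or knockout 2, 4 or 5, and 6 without knockout 6). The 50 of MPP became 84 with a logit and 30 to 165 without 1 library (78 and 165 without floxed control 1 and 3, 114 and 30 without knockout 1 and 2). The 4 of the Myc allele became 0 with a logit and 3 to 306 without 1 library (42 without knockout 6, 306 and 7 without Myc allele 1 and 2). The exact tests of Rxra and Rxrb kept their direction with a pseudocount of 0.1.

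Single genes that reversed had not passed. Myc in all LT-HSC went to -0.066 with median-of-ratios, -0.069 with array weights, -0.103 with median-of-ratios without floxed control 2, and without 1 library ranged from -0.078 (without floxed control 2) to 0.181. In batch 1 Myc went to -0.28, with quantile scaling to -0.11 and with median-of-ratios without floxed control 2 to -0.39, and in batch 2 to 0.12 with either scaling. Without 1 library Rxra ranged from -0.412 to 0.0106 (without knockout 4) in all LT-HSC, from -0.406 to 0.0306 (without floxed control 1) in batch 1, from -0.712 to 0.238 (without knockout 4) in batch 2, from -0.0903 to 0.0129 (without knockout 3) in MPP, and for the Myc allele from -0.695 to 0.256 (without knockout 5), beside 0.406 with array weights. Rxrb in batch 1 ranged from -0.429 to 0.0217 (without floxed control 1). Over all alternatives of single genes, 1405 values kept their direction and their side of the threshold, 334 no longer passed, 12 newly passed and 16 reversed.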

Other observations

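The tests of chromosome segments in this part were fixed before their results were seen, and the genes given as values were chosen after.

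The levels of 3 genes are set side by side over all LT-HSC groups, which no single comparison of the report does. Cyp26b1, the enzyme that clears retinoic acid, stood at 2.68 ± 1.34 TPM (SD, n = 3) in LT-HSC floxed controls, 2.84 ± 1.39 TPM (SD, n = 3) in Cre controls, 0.099 ± 0.11 TPM (SD, n = 3) in batch 1 knockouts, 0.978 ± 1.03 TPM (SD, n = 3) in batch 2 libraries labelled knockout and 0.204 ± 0.251 TPM (SD, n = 3) in the Myc allele group. Olfr632 stood at 1.31 and 1.01 TPM in the controls, 13.2 ± 3.92 TPM (SD, n = 3) in batch 1 knockouts, 2.23 ± 1.01 TPM (SD, n = 3) in batch 2 libraries labelled knockout and 12.9 ± 4.57 TPM (SD, n = 3) in the Myc allele group. Nnt, the mitochondrial transhydrogenase gene, stood at 7.65 TPM in LT-HSC floxed controls, 15.1 TPM in batch 1 knockouts, 24.0 TPM in Cre controls, 7.72 TPM in batch 2 libraries labelled knockout and 8.33 TPM in the Myc allele group, so its means moved in opposite directions in the 2 batches (limma with Benjamini-Hochberg adjusted p = 0.00721 in batch 1, rescaled 0.163, and not passing in batch 2 at 0.281, rescaled 0.242).

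Sva, listed at 0 in floxed control LT-HSC and present in batch 1 knockout LT-HSC and MPP, was listed at 0 in all batch 2 libraries. Among these are Myc allele 1 and 3, whose Rxra exon-skipping junction lay above the control values. Rxra deletion thus came without Sva there, where the Myc allele differs as well. A segment carried along with an allele could bring such a gene, in which case genes called in LT-HSC of batch 1 after rescaling would lie within 5 Mb of it more often than other tested genes. They did not, with 1 called gene near Sva where 2.24 would fall by chance (one-sided Fisher's exact p = 0.9). This argues against a segment with several changed genes at Sva, and a variant that changes a single gene stays open. The same test near Rxra (p = 0.989, Fisher's exact test) and Rxrb (p = 0.776, Fisher's exact test) decides nothing, because both groups of batch 1 carry the floxed alleles.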
